A study of Mus musculus with 12 samples.

How the data were processed

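RNA abundance was measured by sequencing in mouse adipose-tissue-derived mesenchymal stem cells, which are stromal cells isolated from fat. The cells were kept either as 2D single cells attached to a surface or as 3D spheroids, which are rounded cell aggregates. Per the labels, each culture was sampled at 0 h and at 24 h, with 3 libraries in each of the 4 groups and 12 libraries in all. Per the labels' protocols, total RNA was handled with a low-input SMART-seq v4 kit and libraries were made with a stranded TruSeq mRNA kit. The labels do not say how long the spheroids had been forming at 0 h. They also do not say whether replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical only.

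The submitters' processing notes name FastQC 0.11.9, STAR, RSEM and the mouse build GRCm39. The versions of STAR and RSEM, the gene annotation and the settings are not given in the sources used here. The authors deposited expected counts per gene, which are estimates that need not be whole because reads that fit several genes are shared out between them. The authors also deposited log2(TPM + 1) values, that is, transcript abundance scaled by gene length and library size, on a log2 scale with a pseudocount of 1. Column names give day 0 and day 1, which were read as 0 h and 24 h. Between 81.9% and 83.9% of the expected counts above 0 in a library were whole as deposited.

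Samples were grouped by culture and time. The expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with edgeR's expression filter (minimum count 10), which left 14338 of 56748 gene IDs, and libraries were scaled by TMM. A quasi-likelihood model was fitted to all 12 libraries with 1 term per group, which left 8 residual degrees of freedom. The comparisons were 3D against 2D at 0 h and at 24 h, 24 h against 0 h in 2D and in 3D, and the difference between the 3D against 2D changes at 24 h and 0 h. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2 scale with edgeR's prior count.

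The tables used here do not pair these gene IDs with names. None of the 56748 IDs matched the RefSeq gene table for GRCm38.p6, which was the reference supplied. The 49 lists of gene symbols fixed before the data were examined were therefore not tested, and genes are reported by ID. The rule for single genes, also fixed beforehand, took the highest and lowest log2 fold changes among called genes with a mean of at least 10 CPM (counts scaled to a common library size) in the higher group and no overlap between replicates. Its parts that need gene symbols could not be applied. The first gene in each direction is given for each 3D against 2D comparison. The rule ranks fitted values, so where a group has few or 0 counts the rank depends on the prior count and does not show which gene changed most. Where 1 group had 0 counts, the fold is taken against a floor of 3 counts over the group. The lower end of the exact 95% counting interval of the ratio is given beside it. Where it had 1 to 3 counts, the ratio is given with its exact 95% counting interval. Intervals and floors cover counting error only.

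In place of the fixed lists, the mouse cell cycle marker pairs supplied with scran 1.30.0 were used, because they are given by Ensembl ID. This choice was made after the data had been seen. In each pair, the first gene is the more abundant of the pair in 1 phase. Of the 667 marker genes, 666 were in the count table. The pair share is the percent of unequal pairs of a phase in which the first gene had more counts. A list was also formed for each phase, from genes that were first in at least 20 pairs and second in at most 10% of their pairs. These limits were set after the pair shares had been seen and before the lists were tested. The lists held 121 genes for G1, 80 for S and 93 for G2/M, and were tested with camera from limma 3.58.1 at a preset correlation of 0.01. Each test was repeated with an estimated correlation and with fry. Pair shares were compared by exact permutation tests, two-sided, for which 3 libraries against 3 cannot give a p below 0.1.

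The steps were tested on simulated counts with known changes in 200 genes, up and down in equal numbers. All other genes were the same in every group. In the data, 34.4% to 48.5% of genes were called in the comparisons of 2 groups, so the simulated rates may not hold there. For 3D against 2D at 24 h, 68.8% of 2-fold and 81.7% of 4-fold changes were recovered among 13566 genes tested. Of the calls, 7.79% were false (12 genes in 1 draw), which is above the nominal rate. For 3D against 2D at 0 h, 62.2% of 2-fold and 87.1% of 4-fold changes were recovered among 13475 genes, and 3.52% of the calls were false. For 24 h against 0 h in 2D, 65.6% and 90.2% were recovered among 13476 genes, with 4.0% false. For 24 h against 0 h in 3D, 70.2% and 89.8% were recovered among 13775 genes, with 1.28% false. The list test was run on separate simulated counts, in which only the G2/M list was lowered, by 2-fold in 1 of the groups compared. That list was called as lower in each comparison of 2 groups. For 3D against 2D at 0 h, 1 phase list that had not been shifted was also called.

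Alternatives covered other scalings, DESeq2 1.42.0, limma-voom, limma on the deposited log2(TPM + 1) values, other filters and thresholds, the replicate number as a block, the groups compared alone, and leaving out each library in turn.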

Results

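The series set 2D culture of mouse adipose-derived mesenchymal stem cells against 3D spheroid culture at 0 h and 24 h. Library totals lay between 10182600 and 17109600 expected counts. Group means were 14072900 ± 1307800 in 2D at 0 h, 12353900 ± 1729470 in 2D at 24 h, 11767800 ± 1676270 in 3D at 0 h and 13717900 ± 2968270 in 3D at 24 h (SD, n = 3). Between 17022 and 19974 genes had at least 1 count in a library. The 10 most abundant genes took between 5.99% and 9.78% of the counts.

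Libraries of a group resembled each other more than libraries of other groups. Across genes, log2 CPM correlated within groups at 0.968 to 0.984. Between groups the correlations ran from 0.895 to 0.958, and the highest were between 2D at 0 h and 2D at 24 h. Genes are not independent replicates, so these values describe the libraries. No replicate pair agreed within sampling noise: the chi-square per degree of freedom was at least 4.69. The first principal component held 35.1% of the variance and separated 2D from 3D. The second held 27.9% and separated the spheroids at 0 h from those at 24 h, while the third, with 14.3%, separated the 2D groups.

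**Figure D1:**
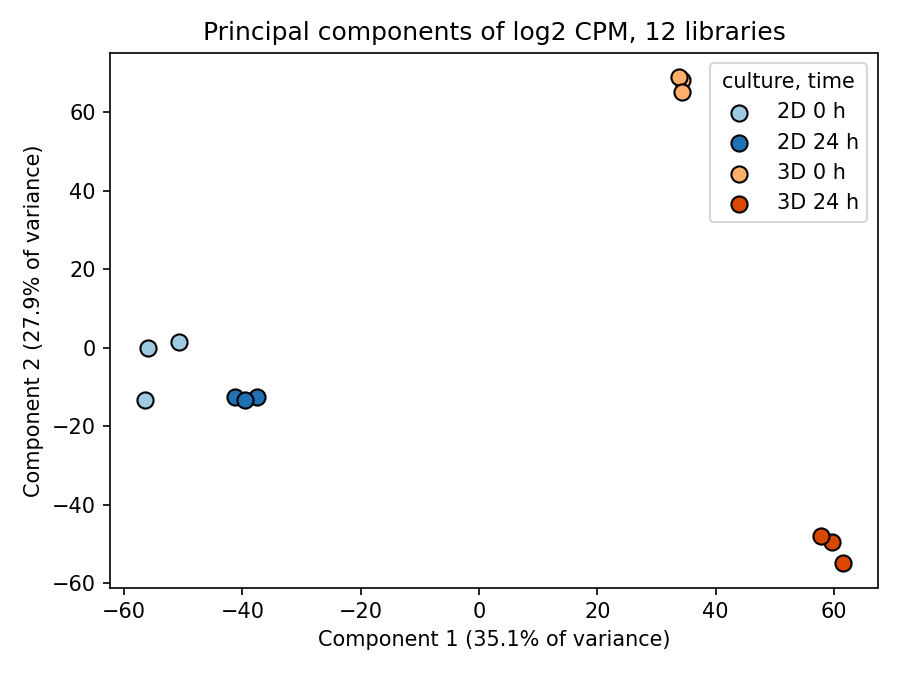
Principal components of log2 CPM for the 12 libraries; the x axis is component 1 (35.1% of the variance), the y axis is component 2 (27.9%), and each point is 1 library coloured by culture and time. The 3D libraries lie to the right of the 2D libraries, and the 3D libraries of 0 h and 24 h lie at opposite ends of component 2.

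The first comparison asked how spheroids differed from 2D cells at 0 h. Expression was higher in 3D for 3309 genes and lower for 3255 of the 14338 tested (edgeR quasi-likelihood test, adjusted p under 0.05). The split depended on the scaling: 4025 were higher and 2610 lower with upper-quartile scaling, and 3641 higher and 2229 lower with limma on the log2(TPM + 1) values. At least 2-fold changes numbered 1566 upward and 1177 downward. At least 4-fold changes numbered 579 and 298. A gene higher in 3D, ENSMUSG00000030406, the first by the rule on fitted values, had 0 counts in 2D at 0 h and 41.1 ± 5.45 CPM in 3D at 0 h (SD, n = 3). From the counts summed over the libraries, it was 552-fold higher in 3D against the floor of 3 counts (edgeR adjusted p = 8.5e-10). It had 448 as the lower end of the exact 95% counting interval of the ratio. At 24 h it stood at 0.0900 ± 0.156 CPM in 2D and 0.199 ± 0.128 CPM in 3D. A gene lower in 3D, ENSMUSG00000109941, taken by the same rule, had 28.9 ± 12.6 CPM in 2D at 0 h and 0 counts in 3D at 0 h. It was 332-fold lower by the same floor (edgeR adjusted p = 3.2e-08), with 269 as the lower end of its interval. It had 0 counts in 2D at 24 h and 7.91 ± 0.911 CPM in 3D at 24 h. Its expected counts were not whole in 6 libraries, which were all those with any counts for it. Its reads were therefore shared with other genes, and its level is uncertain.

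Lists of genes that lead marker pairs of the cell cycle phases were tested next, a choice made after the data had been seen. G2/M covers the phases just before and during cell division, S is the phase of DNA replication and G1 precedes it. None of the 3 lists was called at 0 h. Of 92 G2/M list genes tested, 26 were higher in 3D and 25 lower, with a median log2 fold change of 0.14 (camera adjusted p = 0.98). The S list had 18 higher and 17 lower of 80 (camera adjusted p = 0.96). The G1 list had 23 higher and 36 lower of 116 (camera adjusted p = 0.40).

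The comparison at 24 h asked the same of cultures kept for 24 h. The G2/M list fell as a group in spheroids: 71 of its 92 tested genes were lower in 3D, 5 were higher and 16 were not called. Of these, 57 were at least 2-fold lower. The median log2 fold change of the list was -1.84, with quartiles of -2.51 and -0.47 (camera adjusted p = 1.3e-36, and adjusted p = 1.3e-05 with an estimated correlation). The S list had 33 lower and 10 higher of 80, with a median of -0.23 (camera adjusted p = 0.0086). Its call was lost at adjusted p = 0.15 with an estimated correlation. The G1 list had 43 lower and 9 higher of 116, with a median of -0.19 (camera adjusted p = 0.022). Its call was lost at adjusted p = 0.20 with an estimated correlation.

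Over all genes at 24 h, 2815 were higher and 3276 lower in 3D. At least 2-fold changes numbered 1044 upward and 1535 downward, and at least 4-fold changes 351 and 563. By the same rule, ENSMUSG00000028238, a gene higher in 3D, had 0.0605 ± 0.105 CPM in 2D and 13.6 ± 1.13 CPM in 3D (SD, n = 3; edgeR adjusted p = 2.8e-07). With 2 counts over the 2D libraries, the ratio was 249 with a 95% counting interval of 68.6 to 2061. Both counts came from 2D 24 h replicate 1, and without that library the fitted log2 fold change went from 7.71 to 10.52, a value that depends on the prior count. At 0 h it stood at 0.0460 ± 0.0797 CPM in 2D and 0.223 ± 0.316 CPM in 3D. The test of the difference between the times did not call it (edgeR adjusted p = 0.054). The gene taken for the lower direction, ENSMUSG00000068748, had 29.0 ± 7.19 CPM in 2D and 0.174 ± 0.104 CPM in 3D, a log2 fold change of -7.42 ± 0.43 (SE; edgeR adjusted p = 3.5e-10). At 0 h it stood at 3.62 ± 1.30 CPM in 2D and 1.52 ± 0.297 CPM in 3D. Scaling by library totals moved the median of all genes to 0.12 in this comparison and also at 0 h. The calls then split into 3918 higher and 2697 lower at 0 h. At 24 h they split into 3648 higher and 2708 lower, or 42.6% lower, against 53.8% lower under TMM.

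**Figure D2:**
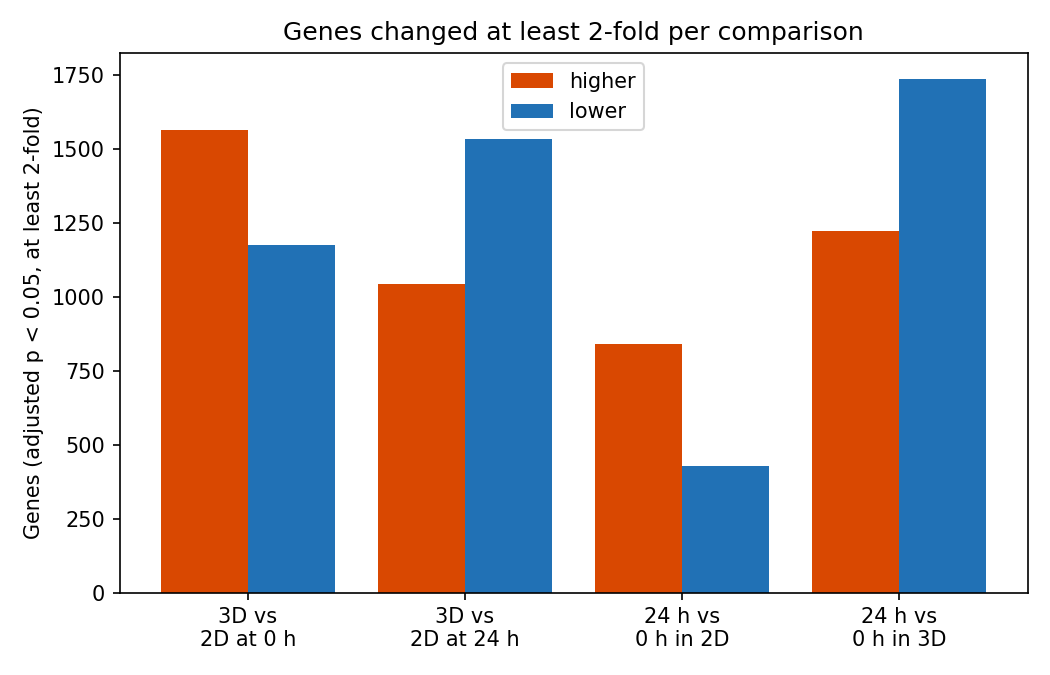
Number of genes changed at least 2-fold under TMM scaling (edgeR adjusted p under 0.05) in each 2-group comparison; the y axis counts genes, orange bars are genes higher in the first-named condition and blue bars are genes lower. The bars for 3D against 2D stand at 1566 higher and 1177 lower genes at 0 h, and at 1044 and 1535 at 24 h.

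Over 24 h in 2D, 2489 genes rose and 2441 fell under TMM. With limma on the log2(TPM + 1) values, 2891 were higher and 1257 lower, and with library totals 2792 and 2083. At least 2-fold changes numbered 840 upward and 429 downward. Fold changes in this comparison went with the relative effective length of the genes (Spearman's rho across genes = 0.33). Of the 92 G2/M list genes, 31 rose and 10 fell, with a median log2 fold change of 0.16 (camera adjusted p = 0.034, and adjusted p = 0.22 with an estimated correlation). The call also ended without 2D 0 h replicate 3 (camera adjusted p = 0.055) and without 2D 24 h replicate 2 (camera adjusted p = 0.058). The S list had 24 higher and 6 lower of 80 (camera adjusted p = 0.034, and adjusted p = 0.25 with an estimated correlation). The G1 list had 32 higher and 14 lower of 116 (camera adjusted p = 0.046, and adjusted p = 0.26 with an estimated correlation).

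Over 24 h in 3D, 3413 genes rose and 3541 fell, with 1222 and 1738 at least 2-fold. The order turned with library totals (3924 higher, 3119 lower) and with limma on the log2(TPM + 1) values (3498 and 2865). The G2/M list fell: 65 of 92 genes were lower at 24 h, 7 were higher and the median log2 fold change was -1.43 (camera adjusted p = 1.3e-28, and adjusted p = 4.1e-05 with an estimated correlation). The S list had 29 lower and 15 higher of 80 (camera adjusted p = 0.14). The G1 list had 33 higher and 31 lower of 116 (camera adjusted p = 0.57). The genes that rose in both cultures numbered 798, where independent lists would share 592 (Fisher's exact test across genes, p = 3.5e-25). Those that fell in both numbered 712, where independent lists would share 603 (Fisher's exact test across genes, p = 3.0e-08). Both tests treat genes as independent, which they are not. A further 1237 genes were called in opposite directions in the 2 cultures, where independent lists would give 1196.

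**Figure D3:**
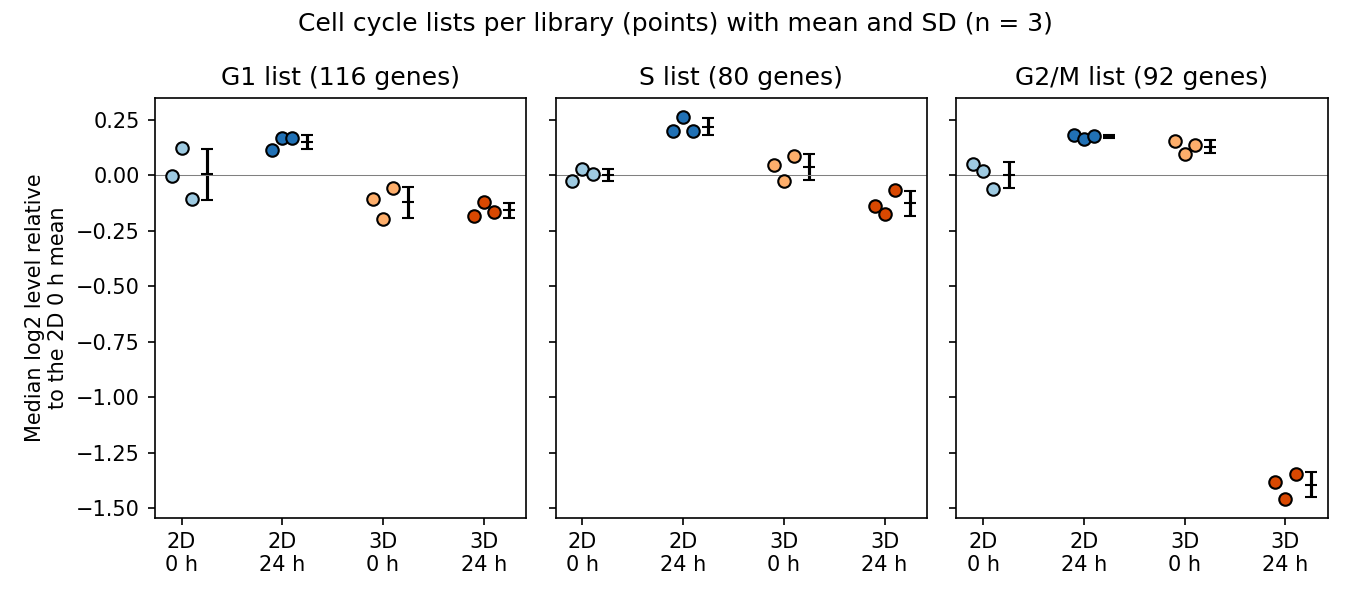
Median log2 level of the G1, S and G2/M lists in each library relative to the mean of 2D at 0 h; the x axis gives culture and time, points are libraries, and the bars beside them are the mean and SD (n = 3). The G2/M list lies at -1.40 ± 0.06 in 3D at 24 h and within 0.2 of 0 in the group means of the other groups.

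The last comparison asked whether the difference between cultures changed with time. It differed between 24 h and 0 h for 5610 genes, of which 2676 had a larger 3D against 2D log2 fold change at 24 h and 2934 a smaller one. The order turned under 5 of 24 alternatives, among them library totals (2845 and 2829), and with limma on the log2(TPM + 1) values the split was 2039 and 2865. Without 1 library, it turned for 2D 0 h replicate 1 (2652 and 2642), 2D 24 h replicate 1 (2857 and 2808), 3D 24 h replicate 1 (2907 and 2840) and 3D 24 h replicate 3 (2547 and 2508). The differences went with relative effective length across genes (Spearman's rho across genes = -0.19). The G2/M list had a median difference of -1.76, with 63 of 92 genes lower and 9 higher (camera adjusted p = 8.8e-28, and adjusted p = 3.7e-05 with an estimated correlation). The S list had 29 lower and 10 higher of 80 (camera adjusted p = 0.0090, and adjusted p = 0.15 with an estimated correlation). The G1 list had 32 lower and 21 higher of 116 (camera adjusted p = 0.50), and its median was 0.03 while its mean was -0.24.

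The differences between cultures at the 2 times overlapped in part. Genes higher in 3D at both times numbered 1139, where independent lists would share 650 (Fisher's exact test across genes, p = 5.9e-120). Genes lower at both times numbered 1250, where independent lists would share 744 (Fisher's exact test across genes, p = 7.0e-118). Both tests treat genes as independent, which they are not. A further 950 genes were called in opposite directions, where independent lists would give 1395. The 2 comparisons share no libraries. Across the 14338 genes, the log2 fold changes at 0 h and 24 h correlated at Pearson's r = 0.28 and Spearman's rho = 0.27, and genes are not independent replicates. Among the 3309 genes higher in 3D at 0 h, the median log2 fold change was 0.96 at 0 h and 0.24 at 24 h. Among the 3255 lower genes it was -0.80 at 0 h and -0.22 at 24 h. The reverse held for genes called at 24 h: the median was 0.79 at 24 h and 0.27 at 0 h among the 2815 higher genes, and -0.94 and -0.22 among the 3276 lower genes. The median absolute log2 fold change of called genes, a different set at each time, was 0.87 at either time.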

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

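The cell cycle lists, the pair shares and the weighing of these patterns were chosen after the data had been seen. The tests of each explanation were written down before their results were seen. The 3D against 2D change differed between 24 h and 0 h, by an edgeR test of that difference, for 5610 genes. By camera on the same difference, it differed for the G2/M list (median -1.76) and the S list (median -0.34). The S list's call did not hold with an estimated correlation (adjusted p = 0.15). Of the single genes, the changes of ENSMUSG00000030406 and ENSMUSG00000109941 differed between the times (edgeR adjusted p = 0.00088 and 6.7e-09). The level of ENSMUSG00000109941 is uncertain, since its reads were shared with other genes. The change of ENSMUSG00000068748 was lower at 24 h by a log2 difference of -6.18 (edgeR adjusted p = 3.7e-07). These genes were picked for extreme changes at 0 h or 24 h in the same libraries. A difference between the times was therefore favoured in advance, and the adjusted p-values do not allow for that. Of 100 regroupings of the 12 libraries, 1, the real one, gave as many genes for the difference between the times, and the highest of the others gave 3292. Regroupings put the culture and time differences into the residual spread, and 85 of the 99 others gave 0 genes. They therefore do not test whether the culture difference changed with time.

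The share of G2/M marker pairs led by the G2/M gene was 42.3% ± 0.165 in 3D at 24 h. It was 53.5% ± 0.558 in 2D at 24 h, 56.4% ± 0.754 in 3D at 0 h and 53.9% ± 1.73 in 2D at 0 h (SD, n = 3). By these counts, all 3D libraries lay above all 2D libraries at 0 h and below them at 24 h. With the deposited TPM values, the libraries overlapped at 0 h (55.3% in 3D replicate 3 and 55.4% in 2D replicate 1). The TPM shares at 24 h were 43.8% ± 0.409 in 3D and 54.7% ± 0.259 in 2D (SD, n = 3). By counts, the change at 24 h minus the change at 0 h was -13.7 percentage points, a difference that was not tested. The same difference for G1 pairs was 17.4 points, with the libraries on opposite sides at the 2 times, and was not tested either. For S pairs it was 1.02 points, with overlapping libraries. The exact permutation test of 3D against 2D at 24 h gave p = 0.1 for G2/M, the smallest it can give, and 0.15 after adjustment over 12 tests. The G1 and G2/M shares are tied, since 41.4% of the G1 pairs have a G2/M list gene as their second member. In those pairs the G1 share was 62.6% ± 1.05 in 3D at 24 h and 39.6% ± 0.145 in 2D at 24 h. In the other G1 pairs it was 53.1% ± 0.265 and 47.3% ± 0.501 (SD, n = 3). The G1 list itself had a median of -0.19 in the same comparison.

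Technical explanations of the lower G2/M share at 24 h were examined. With all libraries thinned to the lowest total, the difference between 3D and 2D at 24 h was -11.2 points, against a sum of SDs of 0.766. The share compares genes within the same library, so thinning could hardly move it, and the result does not decide on library depth. The G2/M list's median of -1.84 lay below the lowest of 10000 random lists matched on effective length and expression (-0.24). For the list, this argues against a bias by length or level. The second genes of the pairs were not matched, so the test does not cover the share itself. A lower share of dividing cells in spheroids after 24 h is a candidate explanation, as a hypothesis only, since the pattern was found and tested on the same libraries. RNA levels alone do not measure division, and a change in the makeup of the cultures stays open and untested.

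The 3D against 2D difference of genes called at 0 h was smaller at 24 h. Genes called at 24 h likewise had a smaller difference at 0 h (0.79 and 0.27 among higher genes, -0.94 and -0.22 among lower genes). The values therefore do not show a loss of the culture difference over time. The median absolute log2 fold change was 0.87 at either time, but it covers genes called separately at each time, so it cannot decide this. Selecting genes for high values at 0 h could shrink later values by itself. With genes called without 1 replicate number, the median signed fold in the held-out libraries at 0 h exceeded that at 24 h in all 3 rotations, by at least 0.58 (log2). With library totals in place of TMM, the larger ratio of the median fold at 24 h to that at 0 h was 0.36. The held-out libraries are also from 0 h, so the first result argues only against spread between libraries as the whole cause. Genes chosen for a difference particular to 0 h would give the same gap, so selection of that kind stays open. Library totals moved the median of all genes only to 0.12 at both times, so they could hardly change the ratio and do not decide on scaling. A change of scaling moves all log2 fold changes of a comparison the same way. The medians instead shrank in both directions, from 0.96 to 0.24 among higher genes and from -0.80 to -0.22 among lower genes. This argues against scaling as the whole cause for genes called at 0 h. The held-out test was not run for genes called at 24 h. How long the spheroids had formed at 0 h stays open.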

How the results depend on the processing

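Alternatives were fixed before the data were examined, except those for the cell cycle lists and the omission of the 50 most abundant genes, which were chosen after seeing the data. Mitochondrially encoded genes, which were to be left out with them, could not be told by ID. The planned tests of the 49 gene lists were not run. Counts of genes, both directions together, stayed within 1.5 times their main value under every alternative except stricter thresholds. The split between higher and lower genes moved with the scaling and the unit, most over time in 2D (2891 higher and 1257 lower with limma on log2(TPM + 1)). Which direction held more genes turned under 2, 4, 5 and 7 of 19 alternatives for 3D against 2D at 0 h and 24 h and for time in 2D and 3D, and under 5 of 24 for the difference between the times. With an added 2-fold limit, 2743 and 2579 genes were called for 3D against 2D at 0 h and 24 h, 1269 and 2960 for 24 h against 0 h in 2D and 3D, 3237 for the difference between the times and 679 for genes changed the same way at both times. At adjusted p under 0.01, 2922 genes were called over time in 2D and 1523 the same way. A smaller count under a stricter limit follows from its construction. Leaving out 1 library gave 5612 to 6509 genes for 3D against 2D at 0 h, 5027 to 5921 at 24 h, 3424 to 5057 over time in 2D and 5938 to 6348 in 3D. It gave 4857 to 5870 for the difference between the times and 1998 to 2438 for the same-way count. The 4 single genes kept their direction and their call in all 44 alternative values.

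The number of lists called at 24 h fell from 3 to 1 with an estimated correlation, and that for the difference between the times from 2 to 1. With fry, 1 list was called at 0 h, 2 over time in 3D and 3 for the difference between the times. Over time in 2D, 0 of the 3 lists were called with an estimated correlation (camera adjusted p = 0.22 for the G2/M list, median 0.16). Leaving out 1 library gave 0 to 3 lists there, and a G2/M median of 0.16 to 0.20. The cause was not tested. The G2/M list's fall in 3D at 24 h kept its call under every alternative run, with medians from -1.84 to -1.68. At this depth, the floor of 3 counts over a group lay between 0.0682 and 0.0842 CPM, so lower levels cannot be ranked.

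Replicate numbers did not pair the samples: same-numbered libraries of different groups correlated at -0.23 to 0.05 in their deviations from the group means, and 11 of 36 best matches were to the own number. With the replicate number as a block, 6127, 5681, 4332 and 6523 genes were called for the 4 comparisons of 2 groups in the order above, 5134 for the difference and 2135 the same way.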

Other observations

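The tests of effective length and the comparison of gene-length trends were chosen after the data had been seen, and the thresholds were set before the test results. Over time in 2D, the log2 fold change went with relative effective length across 14338 genes (Spearman's rho across genes = 0.33). The median log2 fold change was -0.41 in the shortest 10% of genes and 0.38 in the longest 10%. The same rho was 0.09 for 3D against 2D at 0 h, -0.16 at 24 h and 0.02 over time in 3D. For the difference between the times it was -0.19, with medians of 0.18 in the shortest 10% of genes and -0.35 in the longest 10%. Genes are not independent replicates.

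The gene with the second highest mean level stood at 1511 and 1152 CPM in replicates 1 and 2 of 2D at 0 h and at 9545 CPM in replicate 3. It lay between 6499 and 12873 CPM in the other 9 libraries.

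The deposited counts and TPM together give each gene's relative effective length per library, which moves when the mix of transcripts of a gene changes. Among 7934 genes with at least 100 counts in every library, limma called a shift of at least 0.25 (log2) for 119 genes between 24 h and 0 h in 3D, for 55 between 3D and 2D at 24 h, for 13 over time in 2D and for 6 between 3D and 2D at 0 h. With the trend of like-length genes left in, 133, 61, 16 and 4 genes were called. The count without the trend was 0.90 of that with it, over the 4 comparisons, which argues against fragment length as the whole cause. Genes with whole counts in all libraries were called at 0.90 of the rate of other genes, which argues against reads shared between genes. A change of transcript mix in spheroids over 24 h is a candidate explanation, as a hypothesis that was not tested on single transcripts. In fits of the 6 libraries compared alone, 43 genes were called for 24 h against 0 h in 3D, of which 33 were among the 119. The highest of the other splits had 0, but such splits put the group difference into the residual spread, so they give no support. For 3D against 2D at 24 h, 2 genes were called, of which 1 was among the 55. Another split gave as many genes or more over time in 2D (1 against 1) and for 3D against 2D at 0 h (1 against 0).

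The splits of the 6 libraries of each comparison, fitted without the other groups, number 10 with the real one and cannot give a share under 0.05. The real split was 1 of 10 with as many genes in each comparison: 6284 genes for 3D against 2D at 0 h, 6146 at 24 h, 4068 over time in 2D and 7480 in 3D. The highest of the other splits gave 0 in each. Such splits put the group difference into the residual spread, so these values give no support. Of 100 regroupings of the 12 libraries, 1, the real one, gave as many genes changed the same way at both times (2389), and the highest other gave 245. Of the 99 others, 97 gave 0, because regrouping puts the culture and time differences into the residual spread. The regroupings therefore do not test the overlap, for which independent lists would share 1393 genes.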
